A study of Homo sapiens with 8 samples.

How the data were processed

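The series holds 8 libraries from a pooled CRISPR interference screen in MDA-MB231 cells, a human triple-negative breast cancer line. Each library is the set of guide sequences amplified by PCR from the genomic DNA of a cell population and sequenced with 53 nt reads on a NextSeq instrument, per the labels. A single table for the whole series was used. Its values are the authors' deposited counts, whole numbers of reads per guide, with no normalization. Per the submitters' processing notes, MAGeCK 0.5.9.4 and the build GRCh38 were used; their settings and the counting step are not given in the sources used here. The amplicons carry no molecular identifier that the labels mention, so a count is a number of reads, and the spread between libraries, not counting error, sets the precision. Every per-sample column of the table was mapped to a sample by its name.

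The table lists 3643 guides against 766 targets. Targets were sorted into 4 kinds by their names in the file. There were 675 transcription start sites (TSSs) of 107 lncRNA transcripts with NONCODE identifiers (3188 guides) and 9 protein-coding genes (45 guides). Another 2 targets, named for the CAGA-MLP promoter of the reporter, had 10 guides, and 80 targets named NONT had 400 guides and were read as non-targeting from that name. Most targets, 684, had 5 guides. The file does not pair NONCODE identifiers with gene symbols, and 0 of them were found in the RefSeq gene table for GRCh38.p14, so lncRNAs are given by the file's own identifiers. At most 2 lncRNA transcript identifiers per direction are printed for a comparison, with any TSS of theirs, apart from a single guide flagged later. This limit narrows the naming rule below. The lncRNA LIMD1-AS1, which the series title names, was not analysed here by name. Guide sequences were not used here, so neither the genomic position of a guide nor its GC content entered any test.

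Libraries were grouped by their GEO titles into day 5 (early time point), Unsorted, HighGFP and LowGFP, with 2 replicates each. The labels do not say whether the replicates came from separate transductions. The p-values of single guides measure the spread between these libraries, which may be technical. Target p-values compare the ranks of a target's guides with random guide sets, so guides and not libraries are their unit. Total counts ran from 5509180 to 6979644 per library. Replicates of all 4 groups differed by more than counting noise, with a mean chi-square per guide of 11.1 at day 5, 11.4 in Unsorted, 46.2 in HighGFP and 42.9 in LowGFP on 1 degree of freedom, so no library was a copy of another.

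Guides with a mean of at least 20 counts over the 8 libraries were kept, which left out 3 and kept 3640. Counts were scaled by TMM and fitted in R 4.3.3 with edgeR 4.0.16 (glmQLFit and glmQLFTest) in 1 model of 4 group means over all 8 libraries, since 2 libraries per group give a poor estimate of spread alone. The common dispersion was 0.0215, with 12.3 prior and 4 residual degrees of freedom. A guide was called at a Benjamini-Hochberg adjusted p under 0.05. Because MAGeCK was not run here, its rank aggregation was rebuilt on the edgeR guide p-values. The one-sided p-values were ranked over all guides, and each target's ranks within the top 0.25 percentile limit were scored by the alpha-RRA rule. This score was set against 100000 random guide sets of the same size and adjusted by Benjamini-Hochberg per direction at 0.05. The smallest p that this permutation can give is 1e-05. Targets needed 2 kept guides, which left 748 tested, 657 of them lncRNA TSSs; 18 targets with 1 guide were not tested as targets. The target log2 ratio is, in each replicate, the median over guides of the difference in log2 CPM (prior count 2), given as mean ± SD over 2 replicates. The log2 fold change of a guide is edgeR's estimate, and that of a target is the median over its guides.

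The comparisons were HighGFP against LowGFP, HighGFP against Unsorted, LowGFP against Unsorted, and Unsorted against day 5. Gene lists were fixed before the data were examined and tested on their guides with camera from limma 3.58.1 at a preset correlation of 0.01. An estimated correlation was run beside it. Of the 13 lists, 3 had members among the target names: TGF-β receptors, SMADs and co-activators with 4, negative regulators with 1, and the reporter with 2. The other 10 had 0. One of these was the non-targeting list, whose name pattern did not match the file's NONT names and was replaced after seeing them. The remaining 9 held common essential genes or lncRNAs chosen by symbol, and the file gives lncRNAs no symbols. RNF111, TRIM33 and XPO1, protein-coding controls outside the fixed lists, were named after seeing the file's target names. The rule for named targets, also fixed before, took 10 per direction by the smallest p in HighGFP against LowGFP and in Unsorted against day 5, 3 per direction in the other comparisons, all members of the 3 lists, up to 4 members of any other list, and LIMD1-AS1.

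The steps were tested on simulated counts with the real means and library sizes, in 5 runs that each changed 200 of 3640 guides. Their spread followed the trend of the real spread with abundance, without further differences between guides. The shares of unchanged guides and targets called may thus be too low for the real screen. Each changed target had 5 guides, and all of them were given the same change. Guides of a real target differ in strength, so the shares of changed targets called may be too high for the real screen. In HighGFP against LowGFP, 11.7% of targets changed by a log2 of 0.3 were called, 60% at 0.5 and 100% at 1, with 0.0847% of unchanged targets called. In Unsorted against day 5 these shares were 81.7%, 100%, 100% and 0.141%. For single guides they were 5.67%, 22.9%, 78.3% and 0.593% in HighGFP against LowGFP, and 0%, 10.3%, 86.3% and 0% in Unsorted against day 5. Alternatives covered size factors, count filters, DESeq2 1.42.0, a robust fit, a replicate block, the 4 compared libraries alone, other percentile limits and null sets, fry, summed counts, other prior counts, a threshold of 0.10 and each library left out. The planned removal of a GC trend was not run, because the table gives no guide sequences.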

Results

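The screen asked which lncRNA promoters, when silenced, alter the response of breast cancer cells to TGF-β. MDA-MB231 cells carried dCas9-KRAB(ZIM3), a catalytically dead Cas9 fused to a repressor domain that silences transcription where a guide RNA leads it. They also carried a green fluorescent protein (GFP) gene under CAGA repeats, the DNA element bound by SMAD complexes. A library of guides was introduced, and untreated cells were collected at day 5 after transduction. The remaining cells received 5 ng/ml TGF-β from day 7, for 24 h according to the design text and 48 h according to the treatment field of the labels, a difference that the sources do not settle. The treated cells were collected unsorted or as the 15% with the highest (HighGFP) and the 15% with the lowest (LowGFP) fluorescence, in 2 replicates per group.

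Total counts were 5787899 and 5847193 at day 5, 6293045 and 6143260 in Unsorted, 5937906 and 6593551 in HighGFP, and 5509180 and 6979644 in LowGFP. The median count per guide lay between 1361 and 1725, and 1 to 5 guides had no count in a library. Guides named as non-targeting took 11.04% to 11.31% of the counts in every library. Between replicates, log2 CPM had a Pearson r across guides of 0.971 at day 5, 0.973 in Unsorted, 0.893 in HighGFP and 0.903 in LowGFP; guides are not independent replicates. The biological coefficient of variation of guide counts was 8.86% at day 5 and 8.68% in Unsorted, against 19.3% in HighGFP and 18.6% in LowGFP.

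Protein-coding targets are named by symbol, and gene spans are given from RefSeq on GRCh38.p14. TGFBR1 lies on chromosome 9 (99103647 to 99154192) and TGFBR2 on chromosome 3 (30606356 to 30694142). SMAD3 lies on chromosome 15 (67065602 to 67195169), SMAD4 on chromosome 18 (51030213 to 51085042), SKIL on chromosome 3 (170357715 to 170396849) and RNF111 on chromosome 15 (58987663 to 59097419). TRIM33 lies on chromosome 1 (114392790 to 114511203) and XPO1 on chromosome 2 (61477849 to 61538612). The guides' own positions were not used here.

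HighGFP against LowGFP asked which repressed targets shifted cells between a strong and a weak TGF-β reporter response. Guides against TGF-β pathway genes shifted cells in both directions. TGFBR1, the type I receptor, was 16.0-fold lower in HighGFP (log2 ratio −4.00 ± 0.07, SD, n = 2) and SMAD4, the common partner of receptor-activated SMADs, was 8.42-fold lower (−3.07 ± 0.34). Guides against SKIL, which encodes the SMAD co-repressor SnoN, were 6.57-fold higher (2.72 ± 0.15), and those against TRIM33, a ubiquitin ligase described as restraining SMAD4, were 5.97-fold higher (2.58 ± 0.34). In all, 10 of 748 targets passed the test, 3 higher and 7 lower in HighGFP.

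All 4 measured members of the list of receptors, SMADs and co-activators fell, and 4 fell when adjusted over the list alone. Besides TGFBR1 and SMAD4 these were SMAD3 and TGFBR2. SMAD3, a receptor-activated SMAD of the pathway, had a log2 ratio of −1.73 ± 0.20. TGFBR2, the type II receptor, was at −1.03 ± 0.07 (n = 2). The 20 guides of the list had a mean log2 fold change of −2.24 (camera, adjusted p = 1.34e-99; adjusted p = 0.00164 with an estimated correlation). SKIL was the 1 measured member of the negative regulators and rose, over all targets and adjusted over the list alone (camera, adjusted p = 1.29e-56; adjusted p = 0.000594 with an estimated correlation). Both targets in the reporter promoter fell, and 2 fell when adjusted over the list alone. The log2 ratio was −2.91 ± 0.45 for CAGA-MLP1 and −2.99 ± 0.18 for CAGA-MLP2 (camera, adjusted p = 4.17e-71; adjusted p = 0.000222 with an estimated correlation). Outside these lists, TRIM33 rose and RNF111 fell. RNF111, also called Arkadia, is a ubiquitin ligase that marks SKIL for degradation, and its log2 ratio was −2.26 ± 0.18. XPO1 did not pass (−0.12 ± 0.28).

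The 7 targets that fell all had a permutation p of 1e-05, the smallest the test can give, with an adjusted p of 0.00107. SKIL and TRIM33 had the same p in the other direction, with an adjusted p of 0.00374. Most of their guides acted alike. For SKIL all 5 guides were called, with log2 fold changes between 2.48 and 2.78. For TGFBR1 4 of 5 were called, and the remaining guide was at −0.43. One TRIM33 guide was at 0.03 and one SMAD3 guide at −0.11.

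Of 657 lncRNA TSSs, 1 rose and 0 fell. TSS3 of NONHSAT193408.1 was 1.46-fold higher in HighGFP (log2 ratio 0.55 ± 0.14, SD, n = 2; permutation adjusted p = 0.0324). Its 5 guides ran from −0.13 to 0.65, and 1 was called by itself. The call was lost without HighGFP replicate 1 (adjusted p = 0.0648), HighGFP replicate 2 (0.461) or LowGFP replicate 2 (0.965), and with fry (0.170), within a range of 0.00249 to 0.965 over 23 alternatives. TSS10 of the same transcript lay next in rank (0.43 ± 0.15, adjusted p = 0.0524). The lncRNA TSS ranked first in the other direction was TSS5 of NONHSAT124680.2 (−0.35 ± 0.03, adjusted p = 0.237). For lncRNA TSSs rising in HighGFP, 36 had an unadjusted permutation p under 0.05, DESeq2 p-values gave 1 call, fry 13 and summed counts 28. For those falling, 23 had an unadjusted permutation p under 0.05. There edgeR and rank aggregation gave 0 calls, DESeq2 p-values 0, fry 12 and summed counts 19. Chance would give such a permutation p to a share of 0.05 of the 657 TSSs per direction. The counts of 36 and 23 alone thus do not show weaker effects.

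Per guide, 137 were called by edgeR, 62 higher and 75 lower in HighGFP. They included 32 of 45 guides against protein-coding genes, 9 of 10 against the reporter, 93 of 3185 against lncRNA TSSs (2.92%) and 3 of 400 non-targeting guides (0.75%). DESeq2 called 161 lncRNA and 9 non-targeting guides. By edgeR 45 of 400 non-targeting guides (11.2%) had an unadjusted p under 0.05, against 482 lncRNA guides (15.1%). Guides without any effect should give a share of 0.05, so guide p-values in this comparison were too low. By edgeR and rank aggregation 0 of the 80 non-targeting targets were called, with an unadjusted permutation p under 0.05 for 1 upward and 0 downward; DESeq2 and fry called 0 and summed counts 1. Their guides did not shift as a list (camera, adjusted p = 0.681). The lncRNA guide with the lowest value, guide 2 of NONHSAT124680.2 TSS9, had a log2 fold change of −3.12 and was lower in both replicates, while the median of the other guides of that TSS was −0.01. The guide count was 88 with only the 4 compared libraries, 213 with DESeq2 and 221 without HighGFP replicate 2.

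**Figure D1:**
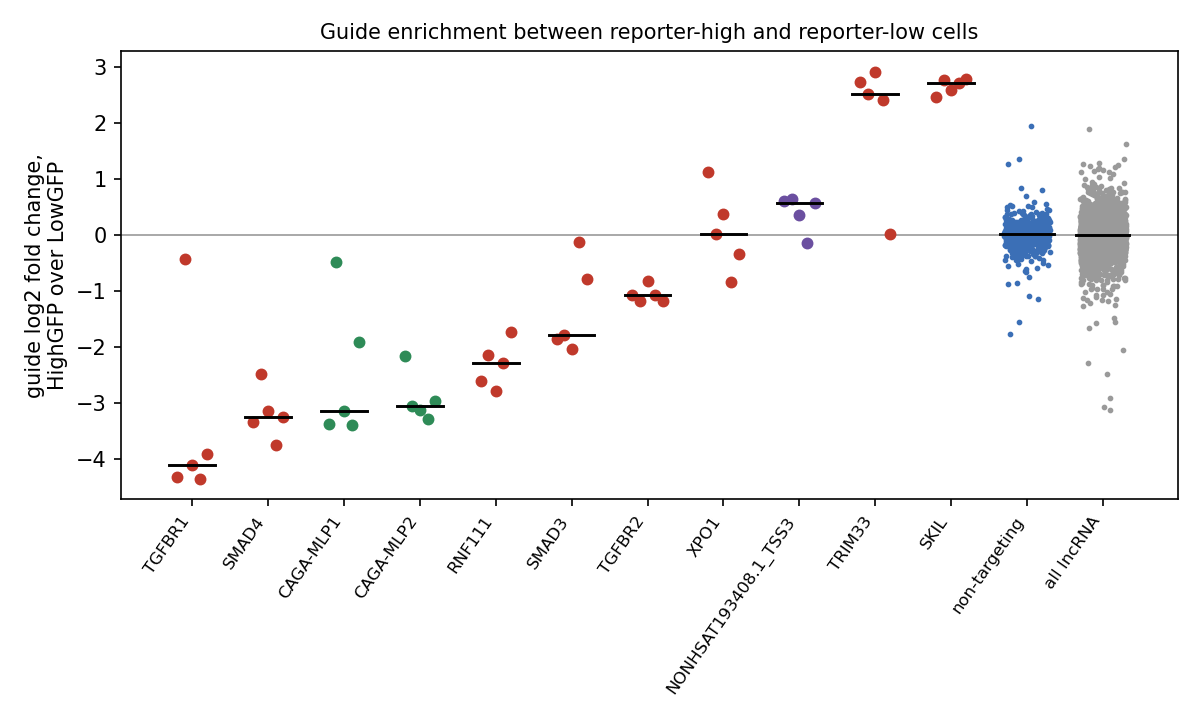
Log2 fold change of each guide in HighGFP over LowGFP (vertical axis), estimated by edgeR from 2 libraries per group. Each point is a guide and each bar a median; reporter targets are green, protein-coding genes red, the called lncRNA TSS purple, the 400 non-targeting guides blue and the 3185 lncRNA guides grey. Guides against TGFBR1, SMAD4, the CAGA-MLP promoter, RNF111, SMAD3 and TGFBR2 have medians between −4.10 and −1.07, and those against TRIM33 and SKIL have medians of 2.52 and 2.72.

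**Figure D2:**
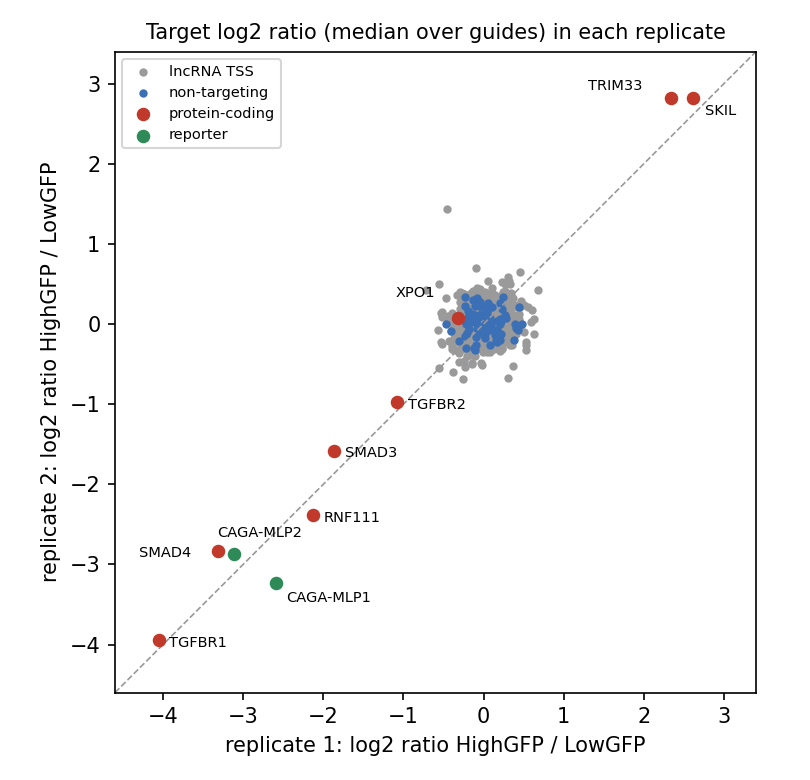
Log2 ratio of HighGFP over LowGFP in replicate 1 (horizontal axis) and replicate 2 (vertical axis) for lncRNA TSSs, non-targeting targets and the named controls, each the median over its guides; the dashed line marks equal values. TGFBR1 was at −4.05 and −3.95 and SKIL at 2.61 and 2.82, outside the cloud of lncRNA and non-targeting targets around 0.

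HighGFP against Unsorted isolated the cells with the strongest reporter response. Guides against SKIL were 3.36-fold higher in HighGFP (log2 ratio 1.75 ± 0.23, SD, n = 2) and guides against TRIM33 3.07-fold higher (1.62 ± 0.01). Guides against TGFBR1 were 2.63-fold lower (−1.40 ± 0.11), those against RNF111 2.54-fold lower (−1.34 ± 0.05), and those against SMAD4 2.29-fold lower (−1.20 ± 0.03). The test called 10 targets, 3 higher and 7 lower.

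Of the 4 receptors and SMADs, 3 fell, and 4 fell when adjusted over the list alone (camera, adjusted p = 2.52e-35; adjusted p = 0.00991 with an estimated correlation). SMAD3 was at −0.74 ± 0.01, with an adjusted p of 0.00499. TGFBR2 did not pass over all targets (−0.24 ± 0.10, permutation adjusted p = 0.787). SKIL, the 1 negative regulator, rose in both adjustments (camera, adjusted p = 1.57e-60; adjusted p = 0.000462 with an estimated correlation). Both reporter targets fell in both adjustments, CAGA-MLP1 at −1.36 ± 0.20 and CAGA-MLP2 at −1.75 ± 0.06 (camera, adjusted p = 2.11e-46; adjusted p = 0.000462 with an estimated correlation). The non-targeting guides did not shift against the other guides as a list (camera, adjusted p = 0.319), while fry, which tests them against no change, gave an unadjusted p of 0.0133. Their median guide log2 fold change was 0.03, and the median of their target medians was at percentile 97.1 of 10000 random lists of targets.

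Among lncRNA TSSs 1 rose and 1 fell; summed counts called 15 higher and 6 lower, and fry 2 and 0. TSS3 of NONHSAT193408.1 was 1.49-fold higher (0.57 ± 0.03, permutation adjusted p = 0.00249), a call lost with fry alone (0.176, within 0.000712 to 0.176 over the alternatives). TSS10 of NONHSAT009852.2 was 1.33-fold lower (−0.41 ± 0.11, adjusted p = 0.0363) and was called in 17 of 23 alternatives, not without HighGFP replicate 1 (0.598), HighGFP replicate 2 (0.122), Unsorted replicate 1 (0.157) or Unsorted replicate 2 (0.103), nor with summed counts (0.161) or fry (0.304), within a range of 0.00321 to 0.598. With fry the calls of SMAD3 (0.176), SMAD4 (0.0730) and TGFBR1 (0.0619) were lost too, each value the highest of its 23 alternatives.

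Of the guides, 57 were called, 20 higher and 37 lower. They included 24 of 3185 lncRNA guides. By edgeR 0 of 400 non-targeting guides were called, 19 had an unadjusted p under 0.05, and DESeq2 called 1. Without HighGFP replicate 2 the count was 105, without Unsorted replicate 1 it was 35, and with DESeq2 it was 87.

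LowGFP against Unsorted isolated the cells with the weakest reporter response. Guides against TGFBR1 were 5.78-fold higher in LowGFP (log2 ratio 2.53 ± 0.29, SD, n = 2) and took 1.14% ± 0.232 of its counts, against 0.220% ± 0.0110 in Unsorted. Guides against SMAD4 were 3.65-fold higher (1.87 ± 0.35), CAGA-MLP1 2.68-fold (1.42 ± 0.06) and CAGA-MLP2 2.52-fold (1.33 ± 0.06). Guides against TRIM33 were 1.97-fold lower (−0.98 ± 0.30) and those against SKIL 1.86-fold lower (−0.89 ± 0.09). The test called 12 targets, 7 higher and 5 lower.

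All 4 receptors and SMADs rose, and 4 rose when adjusted over the list alone (camera, adjusted p = 6.31e-107; adjusted p = 0.00185 with an estimated correlation). SMAD3 was at 0.96 ± 0.16 and TGFBR2 at 0.91 ± 0.28. SKIL fell in both adjustments (camera, adjusted p = 3.75e-18; adjusted p = 0.00314 with an estimated correlation), and both reporter targets rose in both (camera, adjusted p = 3.72e-47; adjusted p = 0.000526 with an estimated correlation). Outside these lists, RNF111 rose (0.95 ± 0.03), TRIM33 fell, and XPO1 did not pass (−0.17 ± 0.18). The non-targeting guides did not shift as a list (adjusted p = 0.792).

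Of the lncRNA TSSs, 3 fell, all of NONHSAT238039.1, and 0 rose by edgeR and rank aggregation or DESeq2. Upward, 15 of 657 had an unadjusted permutation p under 0.05, a smaller share than the 0.05 expected by chance. Summed counts called 6 higher and 5 lower, fry 0 and 2, and random sets from the non-targeting guides 0 and 10. TSS7 was 1.34-fold lower in LowGFP (−0.42 ± 0.12, permutation adjusted p = 0.0125), TSS6 1.30-fold (−0.38 ± 0.06, adjusted p = 0.0464) and TSS3 1.28-fold (−0.36 ± 0.03, adjusted p = 0.0464). In HighGFP against LowGFP none of these 3 TSSs was called, with TSS7 at 0.28 ± 0.22 (permutation adjusted p = 0.484). In LowGFP against Unsorted all 5 guides of each TSS were below 0, and edgeR called none by itself. TSS7 was called in 22 of 23 alternatives (adjusted p from 0.0015 to 0.0726), TSS6 in 18 (0.0015 to 0.581) and TSS3 in 16 (0.0015 to 0.941). TSS3 was lost with a replicate block (0.0509), a percentile limit of 0.10 (0.55) and summed counts (0.190). Leaving out LowGFP replicate 1, LowGFP replicate 2 or Unsorted replicate 2 ended the calls of TSS6 (adjusted p of 0.207, 0.581 and 0.285) and TSS3 (0.941, 0.809 and 0.866), and leaving out Unsorted replicate 1 ended that of TSS6 (0.141). With fry 6 targets were called, and RNF111, SMAD3, SMAD4, TGFBR2, TRIM33 and the 3 TSSs were not, with adjusted p from 0.0581 to 0.604. Each control call in that comparison was kept in the other 22 alternatives.

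Of the guides, 59 were called, 41 higher and 18 lower in LowGFP, among them 24 of 3185 lncRNA guides. By edgeR 0 of 400 non-targeting guides were called, 13 had an unadjusted p under 0.05, and DESeq2 called 1. Without Unsorted replicate 1 the guide count was 38.

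**Figure D3:**
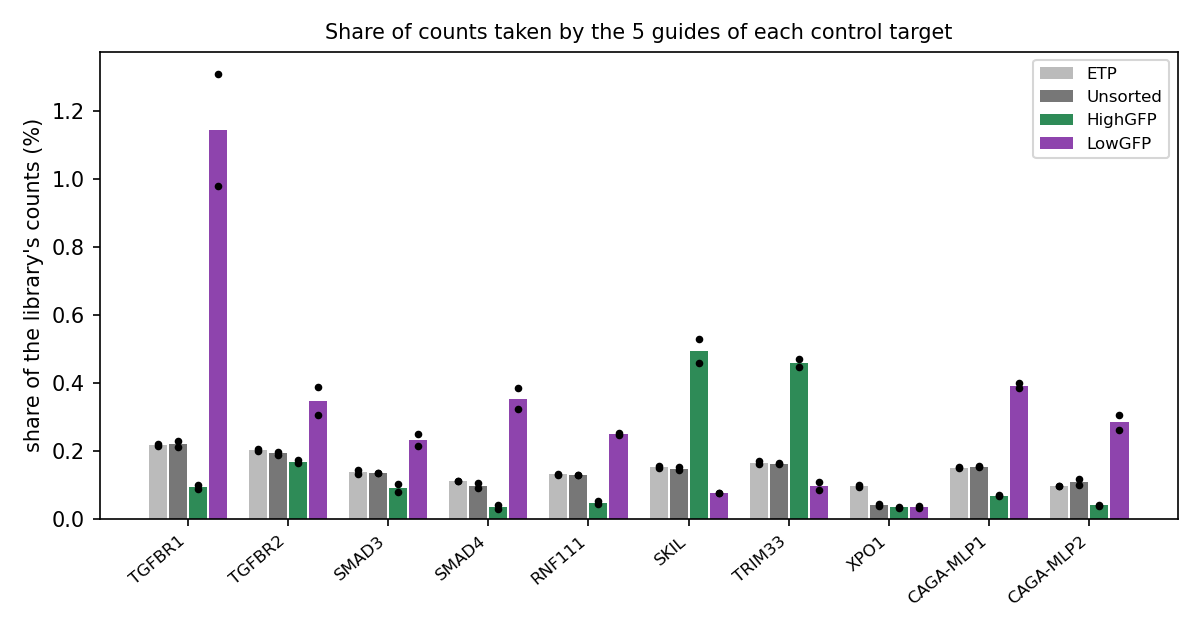
Share of each library's counts taken by the 5 guides of each control target shown, in percent; bars are means of 2 libraries and points the libraries. TGFBR1 guides took 1.14% in LowGFP and 0.0945% in HighGFP, SKIL guides 0.494% in HighGFP and 0.0776% in LowGFP, and XPO1 guides 0.0970% at day 5 and 0.0403% in Unsorted.

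Unsorted against day 5 compared the treated pool with the untreated cells collected earlier, and so follows growth together with the treatment. XPO1, the main nuclear export receptor, was the 1 target called of 748. Its guides fell 3.02-fold (log2 ratio −1.60 ± 0.25, SD, n = 2; permutation adjusted p = 0.00748), from 0.0970% ± 0.00511 of counts at day 5 to 0.0403% ± 0.00400 in Unsorted. All 5 XPO1 guides were below 0, between −1.96 and −0.17. RNF111 (−0.16 ± 0.14) and TRIM33 (−0.04 ± 0.05) did not pass, and neither did any of the receptor, SMAD, SKIL and reporter targets.

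The receptors and SMADs (camera, adjusted p = 0.0725), SKIL (0.556), the reporter (0.125) and the non-targeting guides (0.556) did not shift, and in each of the first 3 lists 0 members passed when adjusted over the list alone. No lncRNA TSS was called by edgeR and rank aggregation, and DESeq2 p-values, fry and summed counts gave 0 as well. Of the 657, 33 had an unadjusted permutation p under 0.05 upward and 31 downward, about the share of 0.05 expected by chance. The TSS with the smallest p upward was TSS8 of NONHSAT238039.1 (0.19 ± 0.01, adjusted p = 0.269), which was called with random sets drawn from the non-targeting guides (0.0150, within 0.0150 to 0.9998 over the alternatives), and downward TSS8 of NONHSAT009852.2 (−0.17 ± 0.10, adjusted p = 0.288).

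No guide was called by edgeR in the fit of all 8 libraries, and DESeq2 called 4. By edgeR 30 of 3640 guides (0.824%) had an unadjusted p under 0.05, among them 1 of 400 non-targeting guides. This is a smaller share than the 0.05 that guides without any effect should give. Without either HighGFP library 3 were called, and without either LowGFP library 1. With the 4 compared libraries alone 18 guides were called, 1 higher and 17 lower; 4 were XPO1 guides (−1.96 to −1.11), 1 was an RNF111 guide (−0.73) and 13 were lncRNA guides. The XPO1 call was kept in 22 of 23 alternatives and lost with fry (adjusted p = 0.535, within 6.46e-06 to 0.535).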

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

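One guide stood out among the 18 targets that had too few guides for a target test. Guide 5 of NONHSAT170675.1 TSS9, the one guide kept for that TSS, had a log2 fold change of 1.15 in HighGFP against LowGFP (edgeR, adjusted p = 0.00036), higher in both replicates at 1.39 and 0.95. In LowGFP against Unsorted it was at −0.84 (adjusted p = 0.012). Its counts were 2082 and 2265 in HighGFP, 728 and 1233 in LowGFP and 1760 and 1761 in Unsorted. With no second guide at this TSS, a target effect was not tested, and 93 guides of lncRNA TSSs passed the same threshold in the first comparison.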

How the results depend on the processing

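Targets called were 10 in HighGFP against LowGFP, 10 in HighGFP against Unsorted, 12 in LowGFP against Unsorted and 1 in Unsorted against day 5. Of the 23 alternatives, 21, 22, 20 and 21 kept these within 1.5 times, and no result reversed. All 9 control calls of HighGFP against LowGFP held in the 23. In place of rank aggregation, fry gave 34 targets in HighGFP against LowGFP, 6 in LowGFP against Unsorted and 0 in Unsorted against day 5. Counts summed per target gave 57, 29 and 20 targets in HighGFP against LowGFP, HighGFP against Unsorted and LowGFP against Unsorted. Random sets drawn from the non-targeting guides gave 19 targets in LowGFP against Unsorted and 2 in Unsorted against day 5; for these target tests the cause was not tested. For guides, the 4 compared libraries alone gave 88 in HighGFP against LowGFP (137 with all 8). In Unsorted against day 5 they gave 18 (0 with all 8). The common dispersion of all 8 libraries, 0.0215, was below those of HighGFP (0.0372) and LowGFP (0.0345). It was above those of Unsorted (0.00754) and day 5 (0.00784). A shared spread too small for the sorted libraries and too large for the others goes with both changes, but was not tested as their cause. DESeq2 gave 213, 87 and 4 guides in HighGFP against LowGFP, HighGFP against Unsorted and Unsorted against day 5; the cause was not tested. Leaving out each library in turn gave 94 to 221 guides in HighGFP against LowGFP, 35 to 105 in HighGFP against Unsorted, 38 to 77 in LowGFP against Unsorted and 0 to 3 in Unsorted against day 5. The highest values came without HighGFP replicate 2 (tied with HighGFP replicate 1 in the last 2) and the lowest of both comparisons of a sorted library with Unsorted came without Unsorted replicate 1; the cause was not tested. Targets ranged over 9 to 12, 9 to 12, 10 to 12 and 1 to 1; a lone remaining library is assumed to vary like the other groups. Among the targets followed by name, 22 calls were gained and 33 lost over all alternatives.

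Same-numbered replicates of different groups deviated together little (correlations of −0.02 to 0.19 across guides), so the main fit did not take the numbers as pairs. The log2 ratios per replicate did match libraries by number. Their SDs thus rest on a matching that may be arbitrary. With a replicate block, targets called were 10, 10, 11 and 1 and guides 142, 56, 61 and 0; the call of NONHSAT238039.1 TSS3 in LowGFP against Unsorted was lost (adjusted p = 0.0509), and list calls were kept. The planned GC correction was not run. At these depths the median guide had 1361 to 1725 counts, and the spread between replicates was above counting error in all 4 groups, so depth alone did not set the precision.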

Other observations

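The tests of whole transcripts, of both gates against Unsorted, of gate shares, of the non-targeting share, of the other guides at a TSS over all called guides, of read depth, of the variance by abundance and of the arrangement of TSSs were chosen after the results were seen; the others were set before the values they measure were known.

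When the TSSs of a transcript were pooled, the mean of several lncRNAs differed from that of random TSSs, though some of their TSSs went the other way. The mean of their TSS medians was set against 100000 random sets of TSSs, for the 77 transcripts with at least 3 TSSs, where the smallest two-sided permutation p is 2e-05. TSSs and not libraries are the unit of this test, so its p-values do not measure the spread between libraries. Random sets also treat TSSs as independent. Any variation that TSSs of a transcript share, whatever its source, could give such calls. In HighGFP against LowGFP 3 transcripts were higher and 1 lower, in HighGFP against Unsorted 3 and 2, in LowGFP against Unsorted 0 and 4, and in Unsorted against day 5 2 and 1. In HighGFP against LowGFP NONHSAT193408.1 had the smallest p (2e-05, adjusted 0.00154). All 10 of its TSSs were above 0, with a mean of 0.26 ± 0.18 (SD over TSSs), 0.24 in replicate 1 and 0.33 in replicate 2, and 40 of 48 guides were above 0. In HighGFP against Unsorted it was at 0.27 (adjusted p = 0.00077) and in LowGFP against Unsorted at 0.01 (adjusted p = 0.919). NONHSAT009852.2 was lower in HighGFP against Unsorted (−0.17, permutation adjusted p = 0.00077), with 10 of 12 TSSs below 0. It was also the 1 transcript called lower in Unsorted against day 5 (−0.07, permutation adjusted p = 0.0118), with 9 of 12 TSSs below 0. Its fall was thus not confined to the sorted cells. NONHSAT238039.1 was lower in LowGFP against Unsorted, at −0.35 ± 0.08 over 8 TSSs (adjusted p = 0.00154), with 36 of 40 guides below 0, and also lower in HighGFP against Unsorted (−0.14, adjusted p = 0.0345); in HighGFP against LowGFP it did not pass (0.16, adjusted p = 0.13). In Unsorted against day 5 it was higher (0.11, adjusted p = 0.00693). The smallest p there was that of NONHSAT108043.2 (mean 0.10, adjusted p = 0.00154), with 11 of 11 TSSs above 0. In LowGFP against Unsorted NONHSAT108043.2 was lower (−0.18, adjusted p = 0.00308), with 10 of 11 TSSs below 0. These comparisons share the Unsorted libraries and are not independent, so the opposite signs were not read as separate effects.

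The mean log2 level of HighGFP and LowGFP was tested against Unsorted, with edgeR and the same rank aggregation. TGFBR1 (log2 0.57, permutation adjusted p = 0.00374), SKIL (0.35, 0.00748), TRIM33 (0.24, 0.0224) and TSS3 of NONHSAT193408.1 (0.33, 0.00374) were above 0. TGFBR2 did not pass (0.35, adjusted p = 0.0509). A mean of log2 ratios does not count cells, so a value near 0 does not show that equal numbers left and entered the gates. With gates of 15%, a guide whose cells all fell in one gate would reach a log2 of 2.74. The median TGFBR1 guide corresponds to 87% of its cells in LowGFP, SMAD4 to 55%, CAGA-MLP1 to 42.6% (5.7% in HighGFP) and TGFBR2 to 28.7%. In HighGFP SKIL corresponds to 49% and TRIM33 to 48%. These shares assume gates of exactly 15% and equal recovery of cells, and the highest TGFBR1 guide comes to 104%, which shows their error.

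TSSs of one transcript resembled each other more than TSSs at large in HighGFP against LowGFP. A chance arrangement is argued against, since permuting the 657 TSS medians over transcripts matched the variance between transcripts in no draw (one-sided permutation p = 1e-04, the smallest that 10000 draws can give; 0.0073 over 627 TSSs without the 3 transcripts that had a called TSS in any comparison). The same permutation p was 1e-04 in each of the other comparisons, Unsorted against day 5 included, so the resemblance is not specific to the reporter. A few extreme guides are argued against as the whole cause, since without the 2 largest guides of each TSS the permutation p was 0.0029. TSSs that lie close together may share silenced chromatin or a neighbouring gene, and this stays open because guide positions were not used here, as does an untested effect of the lncRNA itself.

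In HighGFP against LowGFP, 91 called lncRNA guides belonged to TSSs that were not called, with a mean absolute log2 fold change of 0.97. Repression of similar strength by all guides of the intended TSS is argued against as their general cause. The test took the 92 called lncRNA guides with another guide at their TSS, whether or not the TSS was called. The other guides of these TSSs moved in the same direction by a mean of 0.044 (95% bootstrap interval 0.00955 to 0.0781). This was under the bound of 0.1, in a test chosen after the results were seen. The interval lay above 0, so weaker repression by the other guides stays open, as does a TSS at which 1 guide alone acts. Variation of 1 sort stays open. The 93 lncRNA guides with the largest replicate 1 ratio had a mean replicate 2 ratio of 0.272 in the same direction (0.0521 to 0.491). Of these 93, 54 kept their direction in replicate 2. The 12 non-targeting guides chosen alike had a mean of 0.833 (0.193 to 1.64). Ratios of the 2 replicates had a Pearson r of 0.126 across all lncRNA guides and 0.127 across all non-targeting guides. Variation unrelated to the target also stays open, because lncRNA guides were called more often than non-targeting ones with all 8 libraries (Fisher's exact p = 0.00772; 0.00514 within 10 classes of abundance) but 46 against 2 with the 4 libraries gave p = 0.163, and the requirement that all of these pass was set after 0.00772 and the counts from the 4 libraries were seen. Off-target binding was not tested.

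The sorted libraries varied more between replicates than the others. Read depth is argued against, because totals were similar: the lowest total of a sorted library was 0.875 of the highest total of the others. A small number of sorted cells per guide stays open: it predicts a ratio of 3.86 between the extra variances of the least and the most abundant of 3 classes of guides, and the ratio was 4.93 (95% bootstrap interval 3.67 to 6.68). The same ratio was 3.35 in the Unsorted libraries (2.86 to 3.87), so the gradient is not specific to sorting. A biological explanation was not tested for this pattern.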
